A study of Homo sapiens with 16 samples.

How the data were processed

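CD3+ cells sorted from CD45+ leukocytes of 4 tissues of 2 prenatal donors were profiled by droplet-based single-cell RNA sequencing from the 5' end of transcripts, with a gene-expression library and a TCR-enriched library per tissue and donor (16 in all). The deposited values are whole-number UMI counts per gene and barcode, made with Cell Ranger 5.0.1 on GRCh38, per the submitters' processing notes, without normalization. The matrices held 33538 features, of which 48 had a symbol used more than once. A UMI count collapses copies of the same molecule, so depth is given as UMIs per library and per cell, and intervals on shares (95% exact binomial) and limits for a count of 0 (3 counts of the total) cover counting error only. Groups and donor numbers came from the sample labels, and same-numbered libraries of different tissues come from the same donor. Deviations from tissue means correlated at 0.117 to 0.4425 between same-numbered libraries in all 6 tissue pairs. The 2 libraries of each tissue differed beyond sampling noise (chi-square per degree of freedom 5.89 to 64.7) and shared 0.546 to 2.26% of barcodes.

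Barcodes with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs were kept. Scrublet's automatic threshold, run per library in Scanpy 1.11.5, marked between 0 and 1695 barcodes and was not usable, so the barcodes with the highest doublet scores were marked instead, at a rate that grew in proportion to the number of barcodes in the library. This marked 1 and 24 barcodes in brain replicates 1 and 2, 1811 and 1108 in MLN, 54 and 236 in small intestine and 1979 and 60 in spleen, which were left out. The T gate asked for at least 2 UMIs over CD3D, CD3E, CD3G, TRAC, TRBC1 and TRBC2 and at most 2 UMIs over 21 genes of other lineages. AIF1 carried most of the latter limit: 18.6 to 45.1% of kept barcodes exceeded it with AIF1 and 1.42 to 5.92% without. Counts were summed per library over the T gate, the CD4 gate and the CD8 gate. Genes used by a gate are not reported as results.

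The summed counts were tested with edgeR 4.0.16 (quasi-likelihood F test, robust, TMM, filterByExpr on tissue) in R 4.3.3, with tissue as the only factor over 8 libraries and 4 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were called. The standard error of a log2 fold change was its size divided by the square root of F. Contrasts were brain minus the mean of MLN, spleen and small intestine in each gate, brain minus small intestine, and small intestine minus the mean of MLN and spleen. The difference of the brain effect between gates was tested over 16 sums with the library as a factor. The biological coefficient of variation was 0.242 in the T gate, 0.214 in the CD4 gate and 0.216 in the CD8 gate. On simulated counts the T gate test recovered 31% of genes changed by a log2 of 1 and 67% of those changed by 2 (100 each, 14121 genes tested), and called 12 of 13926 unchanged genes. It recovered 32% and 68% in the CD4 gate and 27% and 70% in the CD8 gate, so a gene without a call may still differ. Of the 31 gene lists, 25 had at least 5 tested genes and were tested in the T gate with camera on limma 3.58.1 (voom) with a preset correlation, with an estimated correlation and with fry. In simulated lists camera called 2 of 2 changed and 0 of 8 unchanged lists, which leaves lists of correlated genes untested.

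Genes were named by a rule: past the threshold with an absolute log2 fold change of at least 1, a mean of at least 30 CPM and brain beyond all 3 peripheral libraries of the same donor in both donors, the 10 largest changes each way in the T gate (64 higher and 275 lower genes met it) and 5 each way elsewhere. Up to 3 called members of each functional list and 19 genes of recirculation, residency and function chosen beforehand were added. Immunoglobulin and TCR segments, mitochondrial and ribosomal genes and sex-linked genes were not named. Coordinates are from GENCODE in GRCh38, in which 92 of 92 named genes were found by identifier. The tests, gates, lists, markers, naming rule and most alternatives were chosen before the data were examined. The share of the CD4 gate was taken unthinned as the main value, since thinning was listed as an alternative, a reading settled after both values were known.

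All kept barcodes were clustered (2000 variable genes without TCR, immunoglobulin, mitochondrial, ribosomal and sex-linked genes, 30 principal components, 20 neighbours, Leiden at resolution 1 in igraph 0.11.9), with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 under Python 3.11.15. A cluster was named where at least 2 markers of a class were among its 10 leading genes, more than of any other class, and was T-like as given with the cluster shares. Microglial RNA in a brain gate was estimated as the level of 5 microglial markers above the periphery, divided by their level in microglia-like brain cells, and this share times a gene's level in those cells gave its predicted microglial part. Shares and TRBV values were compared by two-sided exact permutation over the 28 splits of 8 libraries. Leading TRBV genes needed at least 2 UMIs among 67 TRBV genes, and values are means of 100 random draws of 292 barcodes. Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the donor as a block, T-like clusters in place of the gate, equal cell numbers, a mitochondrial limit of 5%, thinning, and leaving out each library. After seeing the data, 4 more were added: the limit without AIF1, doublets kept, the gate within T-like clusters, and no cells of the cluster led by GNLY and GZMH, together with fry, thinned forms of the gates, the donor block on the thinned share and within T-like clusters, and shared lymphoid libraries. Figures were drawn with Matplotlib 3.10.9.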

Results

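Single-cell RNA sequencing was done on CD3+ T cells that had been sorted from CD45+ leukocyte suspensions of 2 prenatal donors. The tissues were brain, small intestine, spleen and mesenteric lymph node (MLN). Each tissue of each donor gave a gene-expression library and a library enriched for T cell receptor (TCR) transcripts. There were 16 libraries in all, 2 of each kind per tissue. The study set brain T cells against T cells of paired lymphoid organs (MLN and spleen) and of a non-lymphoid organ (small intestine). The gene-expression libraries of donors 1 and 2 held 366 and 1716 barcodes in brain, 15067 and 11792 in MLN, 2604 and 5444 in small intestine, and 15739 and 2738 in spleen. Their total UMI counts (unique molecular identifiers, which count RNA molecules) were 2682333 and 9118077 in brain, 110548950 and 106340536 in MLN, 20538113 and 52337028 in small intestine, and 112606418 and 25847220 in spleen. Barcodes were called T cells by a gate on their own UMIs (at least 2 over the CD3 and TCR constant genes, at most 2 over 21 genes of other lineages). The T gate held 250 and 1251 cells in brain against 1436 to 9058 in the peripheral libraries. It had a median of 5612 and 4603 UMIs per cell in brain and 5334 to 7912 elsewhere. Within it, a CD4 gate (CD4 but no CD8 UMI) held 79 and 302 brain cells and a CD8 gate (CD8A or CD8B but no CD4 UMI) held 84 and 451. Counts were summed per library and gate, and levels are given in CPM of the UMIs of the gate as mean ± SD over libraries.

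Brain T cells carried more RNA of cytotoxic effector genes than T cells of the 3 peripheral tissues, and less RNA of others such as TRAF4 and CREM. GNLY, which encodes the pore-forming granule protein granulysin, stood at 574 ± 201 CPM in brain (n = 2) and 14.8 ± 9.11 CPM in the periphery (n = 6), a log2 fold change of 5.48 (SE 0.21, edgeR quasi-likelihood with Benjamini-Hochberg adjusted p = 1.11e-05). GZMH, encoding the granule protease granzyme H, was at 170 ± 86.3 against 0.605 ± 0.525 CPM (log2 fold change 8.31, SE 0.65, edgeR adjusted p = 0.00188). PRF1, encoding perforin, was at 180 ± 36.6 against 22.2 ± 9.73 CPM (3.10, SE 0.26, edgeR adjusted p = 0.000649). TRAF4, a signalling adaptor, was lower in brain, at 15.9 ± 7.48 against 205 ± 117 CPM (log2 fold change -3.47, SE 0.45, edgeR adjusted p = 0.00374). CREM, a transcription factor that responds to cyclic AMP, was at 81.4 ± 23.2 against 719 ± 507 CPM (-2.93, SE 0.35, edgeR adjusted p = 0.00205). Of 14440 genes tested, 1190 were higher and 1678 lower in brain than in the mean of MLN, spleen and small intestine (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The counts rested on both brain libraries: without brain replicate 1 they were 538 higher and 223 lower, and without brain replicate 2 they were 175 and 79. Fewer were lower without peripheral libraries too: 1098 without MLN replicate 1 and 1063 without small intestine replicate 2. With 250 cells per library 771 were higher and 748 lower, and 1923 were higher with no filter on low counts.

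The 10 genes that rose most under the naming rule were GNLY, GZMH, PRF1, PRDM1, CISH, TSPO, S100A4, CCL4, CCL4L2 and FGFBP2. PRDM1, the transcriptional repressor Blimp-1 of effector differentiation, rose by 3.23 on the log2 scale (SE 0.28) to 135 ± 39.1 CPM, from 15.4 ± 6.56 CPM in the periphery (edgeR adjusted p = 0.000836). CISH, an inhibitor of cytokine and TCR signalling, stood at 105.4 ± 31.0 against 12.0 ± 8.52 CPM (log2 fold change 3.44, SE 0.36, edgeR adjusted p = 0.0023). TSPO, a protein of the outer mitochondrial membrane, was at 107 ± 24.3 against 17 ± 11.8 CPM (3.16, SE 0.18, edgeR adjusted p = 3.63e-05). S100A4, a calcium-binding protein of memory T cells, was at 1112 ± 14.1 against 321 ± 196 CPM (2.11, SE 0.17, edgeR adjusted p = 0.00023). The chemokine genes CCL4 (579 ± 104 against 49.1 ± 36.3 CPM, edgeR adjusted p = 0.00822) and CCL4L2 (125 ± 58.9 against 9.95 ± 6.43 CPM, edgeR adjusted p = 0.00325) rose by 3.73 and 3.75. They are near-identical copies, so the split of counts between them is uncertain. RNA of microglia-like cells was predicted to give 11% of the brain level of CCL4 and 27.6% of that of CCL4L2. FGFBP2, a secreted protein of cytotoxic lymphocytes, was at 92.3 ± 85.0 against 20.3 ± 7.29 CPM (log2 fold change 2.19, SE 0.53, edgeR adjusted p = 0.0396). Its call was lost in every leave-out except that of brain replicate 2 (edgeR adjusted p up to 0.133, without brain replicate 1) and with the donor as a block (edgeR adjusted p = 0.0750). Its direction turned without the cells of the cluster led by GNLY and GZMH (log2 fold change -1.46). CCL4 reached an edgeR adjusted p of 0.0574 without brain replicate 2.

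The 10 genes that fell most were ARG2, HES4, TRAF4, LYPD3, CREM, VPS37B, ZBED3, METRNL, HIC1 and ID3. LYPD3, a surface protein with a lipid anchor, was at 22.2 ± 1.85 CPM in brain and 190 ± 77.0 CPM in the periphery (log2 fold change -3.07, SE 0.31, edgeR adjusted p = 0.000836). HIC1, a transcriptional repressor, fell to 6.54 ± 0.537 from 47.4 ± 28.6 CPM (-2.67, SE 0.26, edgeR adjusted p = 0.000532). ID3, an inhibitor of E-protein transcription factors, was at 32.2 ± 1.22 against 203 ± 64.6 CPM (-2.64, SE 0.39, edgeR adjusted p = 0.00512). ARG2, a mitochondrial arginase, had 20 UMIs in the brain T gate and a level of 2.12 ± 0.620 against 56.5 ± 43.2 CPM (-4.30, SE 0.73, edgeR adjusted p = 0.0126). HES4, a basic helix-loop-helix repressor, was at 4.23 ± 3.6 against 116 ± 152 CPM (-3.55, SE 0.85, edgeR adjusted p = 0.0384). VPS37B, a subunit of an endosomal sorting complex, was at 45.9 ± 5.68 against 322 ± 116 CPM. METRNL, a secreted protein, was at 15.4 ± 1.19 against 101 ± 31.5 CPM, and ZBED3 at 5.96 ± 0.507 against 43.4 ± 23.8 CPM. The edgeR adjusted p without brain replicate 2 was 0.135 for ARG2, 0.0883 for ID3, 0.0827 for VPS37B, 0.0749 for ZBED3 and 0.0705 for METRNL, and without brain replicate 1 it was 0.0766 for ARG2 and 0.0593 for ID3. Of the leave-outs, HES4 kept its call only without each of the MLN libraries, and it lost it without the cluster led by GNLY and GZMH (edgeR adjusted p = 0.118). Its edgeR adjusted p was up to 0.156 without a brain library, 0.0656 without a spleen library and 0.0628 without a small intestine library. With the donor as a block it was 0.0858 in edgeR.

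In the GRCh38 coordinates of the GENCODE 29 annotation, GNLY (ENSG00000115523) spans 85685175 to 85698854 on the plus strand of chromosome 2 and GZMH (ENSG00000100450) spans 24606480 to 24609699 on the minus strand of chromosome 14. PRF1 (ENSG00000180644) lies at 70597348 to 70602775 on the minus strand of chromosome 10 and PRDM1 (ENSG00000057657) at 106086320 to 106109939 on the plus strand of chromosome 6. TSPO (ENSG00000100300) occupies 43151514 to 43163242 on the plus strand of chromosome 22 and CCL4 (ENSG00000275302) 36103590 to 36105621 on the plus strand of chromosome 17. Among the lower genes, TRAF4 (ENSG00000076604) is at 28743984 to 28750958 on the plus strand of chromosome 17, CREM (ENSG00000095794) at 35126791 to 35212958 on the plus strand of chromosome 10 and ID3 (ENSG00000117318) at 23557918 to 23559794 on the minus strand of chromosome 1. All are annotated as protein-coding genes, and each level counts UMIs over the whole gene.

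**Figure D1:**
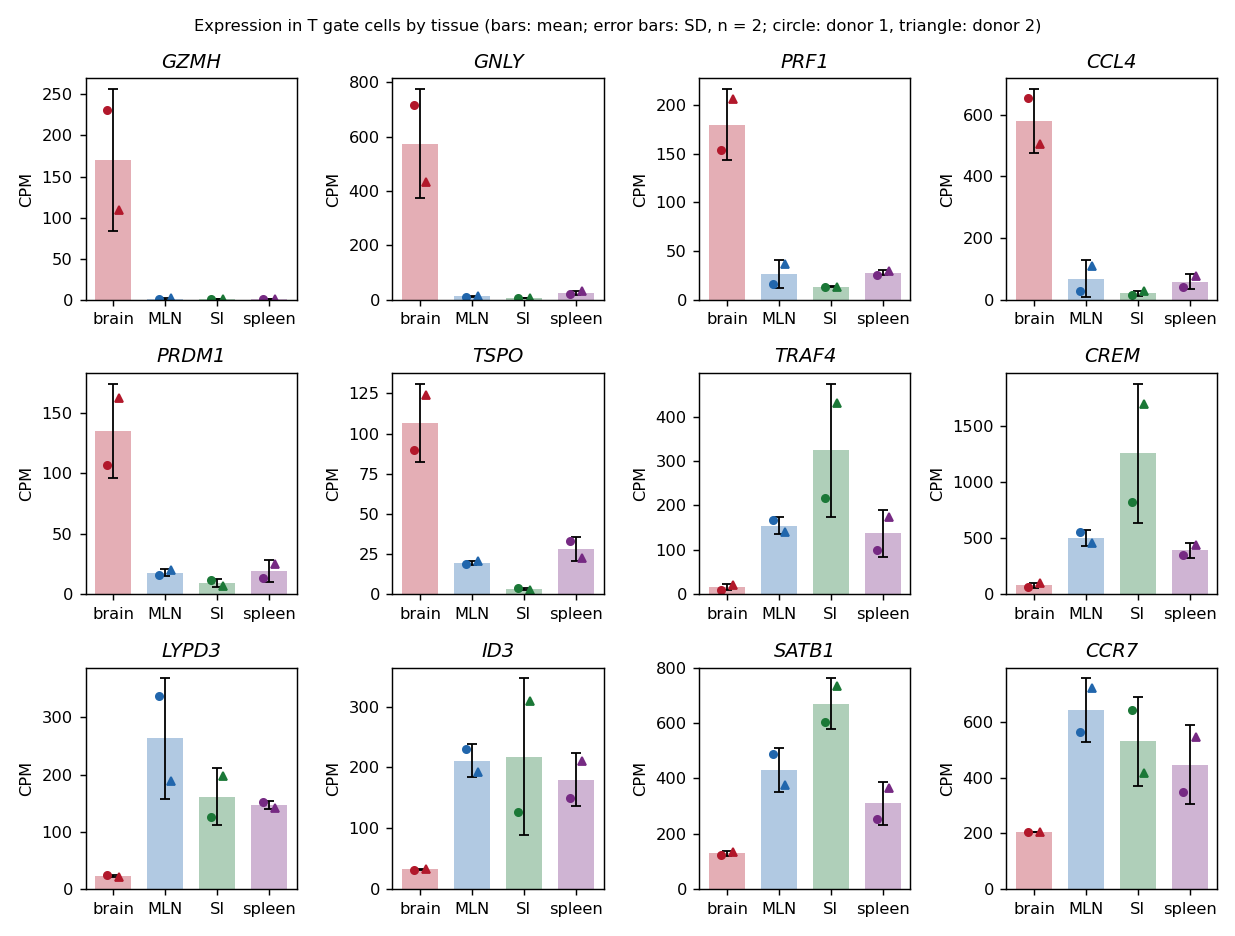
Levels in CPM (vertical axes, each starting at 0) of 12 genes in T gate cells of brain, mesenteric lymph node (MLN), small intestine (SI) and spleen, where bars give the mean, error bars the SD (n = 2), circles donor 1 and triangles donor 2. GZMH, GNLY, PRF1, CCL4, PRDM1 and TSPO lie above every peripheral library in both brain libraries, and TRAF4, CREM, LYPD3, ID3, SATB1 and CCR7 below.

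Of 25 gene lists fixed beforehand and large enough to test, 10 passed camera's test against the other genes in the T gate (Benjamini-Hochberg adjusted p under 0.05 with a preset correlation between genes). All 10 calls were lost when that correlation was estimated from the data. Cytotoxicity genes led: 13 of 17 tested members rose (14 rose and 1 fell when adjusted over the list alone). Among them were EOMES and TBX21, transcription factors of effector cells. GZMA, encoding granzyme A, was at 254 ± 62.1 against 85.5 ± 44.7 CPM. The camera adjusted p was 9.72e-12 and the adjusted p = 0.169 with an estimated correlation. Homing receptors followed, with 12 of 20 members higher and 2 lower (13 and 2 adjusted over the list alone; camera adjusted p = 2.19e-06, and adjusted p = 0.131 with an estimated correlation). CX3CR1, the fractalkine receptor, was at 21.9 ± 6.28 CPM in brain and 0.254 ± 0.272 CPM in the periphery (edgeR adjusted p = 1.42e-05), with 32.2% of the brain level predicted from microglial RNA. CCR2, a receptor of monocyte-attracting chemokines, was at 10.2 ± 6.47 against 0.628 ± 0.325 CPM. CCR4, a receptor of skin-homing and helper T cells, fell to 18.7 ± 5.05 from 79.7 ± 66.3 CPM. CCR1 stood at 4.72 ± 5.88 CPM in brain against 0.369 ± 0.241 CPM. CCL3, a chemokine gene of the cytotoxicity list, was at 63.6 ± 45.6 against 2.44 ± 2.78 CPM, with 55.0% of its brain level predicted from microglial RNA. The edgeR adjusted p without brain replicate 2 was 0.804 for CCR1, 0.0982 for CCR2, 0.0506 for CCR4, 0.146 for CCL3 and 0.0745 for GZMA. CCL3 also lost its call without brain replicate 1 (0.0630), small intestine replicate 1 (0.0914) and small intestine replicate 2 (0.0792). It had 0.0525, and GZMA 0.0831, without the cluster led by GNLY and GZMH.

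Memory and activation genes shifted towards brain, with 10 of 18 members higher and 4 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.262 with an estimated correlation). LGALS1, the lectin galectin-1, rose to 138 ± 30.3 from 39.6 ± 14.7 CPM (edgeR adjusted p = 0.00305). CD38, an ectoenzyme of activated and immature lymphocytes, fell to 27.5 ± 8.78 from 120 ± 47.6 CPM (edgeR adjusted p = 0.000532). Interferon-response genes had 8 of 22 members higher (11 adjusted over the list alone; camera adjusted p = 5.87e-05, and adjusted p = 0.617 with an estimated correlation). IFI44L was at 55.3 ± 50.5 CPM in brain against 2.71 ± 1.29 CPM, IFI27 at 14.5 ± 15 against 0.248 ± 0.145 CPM and IFIT3 at 60.5 ± 43.5 against 13.5 ± 13 CPM. Type 17 and innate-like genes had 3 of 14 members higher and 1 lower (also 3 and 1 adjusted over the list alone; camera adjusted p = 0.0402, and adjusted p = 0.692 with an estimated correlation). Among the higher members were MAF at 54.9 ± 11.1 against 23.0 ± 11.5 CPM and CTSH, a lysosomal protease, at 26.9 ± 4.75 against 7.33 ± 4.47 CPM. The camera adjusted p without brain replicate 2 was 0.606 for the interferon list and 0.968 for the type 17 list, with its direction turned. In edgeR the adjusted p was then 0.0569 for IFI27, 0.0543 for CTSH and 0.0703 for LGALS1. IFIT3 kept its call only without small intestine replicate 2 (edgeR adjusted p up to 0.369, without brain replicate 2). Without the cells of the cluster led by GNLY and GZMH, which leaves 124 and 638 brain cells, the camera adjusted p was 0.700 for memory and activation, with its direction turned, 0.254 for interferon response and 0.432 for type 17 genes. The edgeR adjusted p was then 0.871 for LGALS1, 0.0721 for IFIT3, 0.232 for MAF and 0.356 for CTSH.

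Markers of NK cells and innate lymphoid cells were among the lists that moved, with 5 of 13 members higher in brain and 2 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.0137, and adjusted p = 0.617 with an estimated correlation). The call was lost without brain replicate 2 (camera adjusted p = 0.0565) and without the cluster led by GNLY and GZMH (0.0787). Of 8 microglia and macrophage markers outside the gate's own genes, 6 were higher in brain (7 adjusted over the list alone; camera adjusted p = 7.61e-09, and adjusted p = 0.169 with an estimated correlation). From 5 marker genes (P2RY12, TREM2, TMEM119, APOE and MRC1), microglia-like cells accounted for an estimated 0.338% of T gate UMIs in brain replicate 1 and 0.804% in brain replicate 2, and 0.254% and 0.195% once the gate was kept to T-like clusters. Markers of gamma-delta T cells had 1 member higher and 1 lower of 8 (2 and 1 adjusted over the list alone; camera adjusted p = 0.217, and 0.0107 upward without brain replicate 2). Neural markers had 2 of 5 lower (also 2 adjusted over the list alone; camera adjusted p = 0.187, and 0.0477 downward under fry). Thymocyte markers had 1 higher and 2 lower of 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.615). Their median log2 fold change was 0.20 but the mean -0.26. Genes of RNA quality (mitochondrial transcripts and nuclear long RNAs) had 0 of 10 members called by edgeR, with 1 at an unadjusted p under 0.05 and 1 called by DESeq2 (0 adjusted over the list alone; camera adjusted p = 0.667). Erythroid markers had 0 of 6 called by edgeR, 0 at an unadjusted p under 0.05 and 0 called by DESeq2 (0 adjusted over the list alone; camera adjusted p = 0.615). Their median was -0.94 and their mean -0.79, although camera ranked the list upward.

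Genes of the fetal T cell program were lower as a list: 6 of 12 members were lower in brain (8 adjusted over the list alone; camera adjusted p = 8.16e-05, and adjusted p = 0.131 with an estimated correlation). SOX4, a transcription factor of immature lymphocytes, was at 111 ± 25.9 CPM in brain and 361 ± 75.5 CPM in the periphery (log2 fold change -1.70, SE 0.19, edgeR adjusted p = 0.000836). Cholesterol and lipid synthesis had 10 of 21 members lower (10 adjusted over the list alone; camera adjusted p = 0.000257, and adjusted p = 0.447 with an estimated correlation). INSIG1, a sensor of cellular sterol, fell to 35.3 ± 0.0617 from 155 ± 67.7 CPM (edgeR adjusted p = 0.000751). SC5D, an enzyme of late cholesterol synthesis, fell to 17 ± 1.29 from 67.0 ± 15.5 CPM (edgeR adjusted p = 0.00062). DHCR7, the last enzyme of the pathway, was at 13.1 ± 7.44 against 56.8 ± 16.7 CPM (edgeR adjusted p = 0.00871, and 0.0572 without brain replicate 1). Glycolysis and hypoxia genes had 8 of 21 members lower (10 adjusted over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.447 with an estimated correlation). PGK1, phosphoglycerate kinase, was at 331 ± 29.6 against 665 ± 136 CPM. PFKFB3, a regulator of glycolytic flux, was at 32.1 ± 12.1 against 117 ± 76.9 CPM, and the hypoxia-inducible ANKRD37 at 14.1 ± 4.10 against 43.5 ± 13.5 CPM. PGK1 had an edgeR adjusted p of 0.0962 without brain replicate 1 and 0.0876 without brain replicate 2. PFKFB3 kept its call only without MLN replicate 1, MLN replicate 2 and spleen replicate 1 (edgeR adjusted p up to 0.228, without brain replicate 1). ANKRD37 kept its call only without each small intestine or spleen library (up to 0.196, without brain replicate 1). PFKFB3 also lost its call with RLE (edgeR adjusted p = 0.0521), equal cell numbers (0.0530) and no cells of the cluster led by GNLY and GZMH (0.0881), and ANKRD37 in T-like clusters (0.0529), with equal cell numbers (0.0585) and without that cluster (0.0718). Without that cluster the camera adjusted p of the fetal list was 0.196.

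No other functional list passed camera's test in the T gate against the 3 tissues together, but each of these except proliferation had members that did. Naive and egress genes had 2 of 14 higher and 5 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.205). The tissues differed for this list: against MLN and spleen alone it had 0 higher and 4 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.000353, downward, and adjusted p = 0.1645 with an estimated correlation), against small intestine 7 higher and 4 lower (camera adjusted p = 0.544). SATB1, a chromatin organizer of naive T cells, was at 129 ± 8.79 against 471 ± 177 CPM (edgeR adjusted p = 0.00092). BACH2, a repressor of effector genes, was at 55.5 ± 1.58 against 197 ± 54.9 CPM (edgeR adjusted p = 0.000532). Tissue residency had 5 of 16 higher and 3 lower (also 5 and 3 adjusted over the list alone; camera adjusted p = 0.467). ZNF683, the residency factor Hobit, was at 76.2 ± 63.5 against 12.0 ± 5.52 CPM and CD101 at 5.23 ± 0.265 against 1.26 ± 0.945 CPM. NF-kB targets had 3 of 19 higher and 6 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.121, and 0.0131 with the donor as a block). The subunit gene REL was at 123 ± 0.591 against 595 ± 230 CPM (edgeR adjusted p = 0.000789) and NFKB2 at 42.1 ± 16 against 242 ± 195 CPM. Regulatory T cell genes had 3 of 15 lower (4 adjusted over the list alone; camera adjusted p = 0.284). These were CCR4, TNFRSF1B at 86.8 ± 37.2 against 196 ± 41.1 CPM and LRRC32 at 2.35 ± 0.940 against 12.4 ± 8.27 CPM. Inhibitory receptors had 1 of 12 higher and 3 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.683). LAG3 was at 33.8 ± 16.1 against 5.81 ± 4.06 CPM, BTLA at 8.17 ± 1.13 against 20 ± 10.2 CPM and TOX2 at 12.5 ± 1.04 against 25 ± 8.99 CPM. Leaving out brain replicate 2 raised the edgeR adjusted p to 0.114 for CD101, 0.0810 for NFKB2, 0.0506 for CCR4, 0.0569 for TNFRSF1B, 0.208 for LAG3, 0.169 for BTLA and 0.158 for TOX2. Leaving out brain replicate 1 raised it to 0.0985 for NFKB2, 0.183 for TNFRSF1B, 0.0631 for LAG3, 0.0528 for BTLA and 0.136 for TOX2. ZNF683 lost its call without MLN replicate 1 (edgeR adjusted p = 0.0521), MLN replicate 2 (0.0541) and small intestine replicate 1 (0.0529), and LAG3 without spleen replicate 2 (0.0520). LRRC32 lost it in every leave-out except those of the MLN libraries (up to 0.220). With the cluster led by GNLY and GZMH removed, the edgeR adjusted p was 0.317 for CD101, 0.104 for LAG3, 0.241 for TOX2, 0.224 for LRRC32 and 0.0939 for TNFRSF1B, and with equal cell numbers 0.0808 for TOX2 and 0.0792 for TNFRSF1B. The camera adjusted p without brain replicate 2 was 0.00198 for NF-kB targets and 0.0153 for regulatory T cell genes.

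Secreted factors went both ways, without a call for any of their lists. Angiogenic factors had 6 of 19 members higher and 4 lower (8 and 5 adjusted over the list alone; camera adjusted p = 0.205, and 0.0384 without brain replicate 1). PDGFA, a platelet-derived growth factor chain, had 5 UMIs in the brain T gate and lay at 0.376 ± 0.532 against 8.52 ± 1.98 CPM (edgeR adjusted p = 0.00172), with 35.3% of its brain level predicted from microglial RNA. SPP1, encoding osteopontin, lay at 50.8 ± 56.9 against 0.162 ± 0.214 CPM (edgeR adjusted p = 0.00763). It had 0 UMIs in small intestine (a limit of 0.0635 CPM) and 76.9% of the brain level predicted from microglial RNA. CCL2 lay at 2.91 ± 3.33 against 0.179 ± 0.331 CPM, with 146% predicted. VEGFA, the main angiogenic growth factor, was at 0.656 ± 0.136 against 3.25 ± 1.88 CPM (edgeR adjusted p = 0.0226) from 6 brain UMIs. Neurotrophic factors had 2 of 13 higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.345). OSM, the cytokine oncostatin M, rose to 44.7 ± 13.2 from 4.21 ± 2.22 CPM (edgeR adjusted p = 0.00115). AREG, an EGF-family growth factor, was at 73.8 ± 15.6 against 45 ± 19.1 CPM and MANF at 41.9 ± 7.77 against 93.4 ± 67.6 CPM. Cytokines had 4 of 17 higher and 3 lower (also 4 and 3 adjusted over the list alone; camera adjusted p = 0.205, and 0.0383 without brain replicate 1). Against MLN and spleen alone they had 4 higher and 0 lower (also 4 and 0 adjusted over the list alone; camera adjusted p = 0.0301, upward, and adjusted p = 0.297 with an estimated correlation). IL22, a cytokine that acts on epithelium, was at 6.86 ± 7.32 against 0.188 ± 0.316 CPM and TNFSF11 at 1.16 ± 0.0589 against 9.15 ± 9.84 CPM. CSF2 had 0 UMIs in the brain T gate (a limit of 0.416 CPM) against 1.57 ± 1.53 CPM. The edgeR adjusted p without brain replicate 2 was 0.519 for CCL2, 0.216 for VEGFA, 0.145 for AREG, 0.121 for MANF, 0.345 for IL22, 0.197 for TNFSF11 and 0.328 for CSF2. Without brain replicate 1 the edgeR adjusted p was 0.116 for VEGFA, 0.192 for MANF, 0.0867 for TNFSF11 and 0.113 for CSF2. Gate settings ended calls as well: IL22 had an edgeR adjusted p of 0.0544 in T-like clusters and 0.0513 without AIF1 in the other-lineage limit, AREG 0.0624 and 0.106, and SPP1 0.0862 with equal cell numbers. Without the cluster led by GNLY and GZMH the edgeR adjusted p was 0.334 for AREG, 0.122 for CSF2, 0.112 for TNFSF11 and 0.131 for VEGFA. CSF2 also missed the threshold without MLN replicate 1 (0.0534), small intestine replicate 1 (0.0555) and small intestine replicate 2 (0.0625).

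Immediate early and stress genes split, with 4 of 22 higher and 5 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.683, and 0.0110 without brain replicate 2, downward). JUN, a subunit of the AP-1 transcription factor, was at 2451 ± 1085 against 989 ± 404 CPM. The mitochondrial chaperones HSPD1 and HSPE1 were at 142 ± 32.3 against 541 ± 173 CPM and 135 ± 5.40 against 372 ± 132 CPM. Proliferation genes had 0 of 20 members called by edgeR, with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 (0 adjusted over the list alone; camera adjusted p = 0.559, and 0.000139 without brain replicate 2, downward). In edgeR the adjusted p was 0.157 for JUN, 0.108 for HSPD1 and 0.193 for HSPE1 without brain replicate 2. Without brain replicate 1 it was 0.128 for HSPD1 and 0.176 for HSPE1, with 0.0550 for HSPE1 without small intestine replicate 2. Under fry, which tests whether a list's genes move on balance 1 way without comparing them with other genes, the cytotoxicity (adjusted p = 0.00559), homing (0.00278), fetal (0.00278) and memory (0.00565) lists kept their calls, as did glycolysis and cholesterol synthesis (0.0495 each). In the same test interferon response (0.242) and type 17 genes (0.355) lost theirs.

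**Figure D2:**
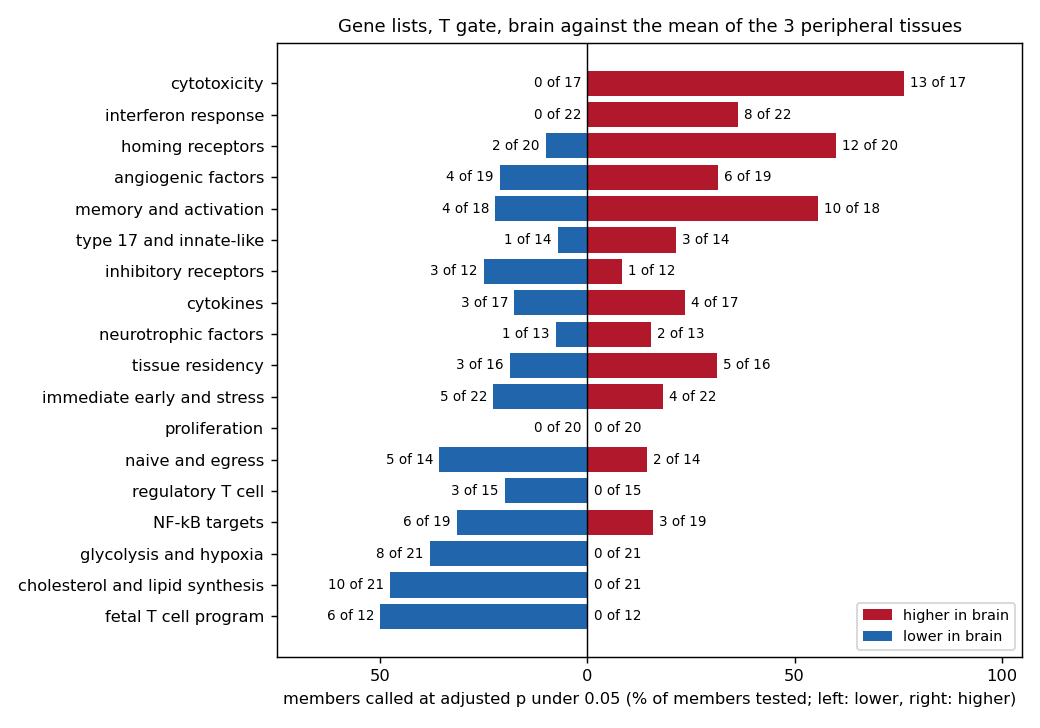
Share of tested members (horizontal axis, %) of 18 functional gene lists called higher (right, red) or lower (left, blue) in the brain T gate than in the mean of the 3 peripheral tissues by edgeR, with the counts beside each bar. Cytotoxicity had 13 of 17 members higher, and the fetal T cell program had 6 of 12 lower.

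Genes chosen beforehand for T cell recirculation, residency and function went both ways. CCR7, the lymph node homing receptor, was lower in brain, at 206 ± 0.452 against 541 ± 140 CPM (log2 fold change -1.38, SE 0.24, edgeR adjusted p = 0.00594). S1PR1, the egress receptor (104 ± 1.73 against 166 ± 57.9 CPM, edgeR adjusted p = 0.0636), missed the threshold. KLF2, a regulator of egress, was at 762.4 ± 1.11 against 573 ± 307 CPM (log2 fold change 0.64, edgeR adjusted p = 0.0278). Small intestine set this difference, with 206 ± 11.6 CPM there, 815 ± 22.1 CPM in MLN and 699 ± 231 CPM in spleen. CD69, an early activation and retention marker, was at 1609 ± 440 against 948 ± 190 CPM (0.77, edgeR adjusted p = 0.0396). The integrin genes of tissue-resident cells ITGAE (38.3 ± 1.01 against 72.6 ± 37.4 CPM) and ITGA1 (4.29 ± 0.525 against 17.6 ± 17.4 CPM) were lower, with log2 fold changes of -0.80 and -1.35 (edgeR adjusted p = 0.0159 and 0.00567). ITGA1 was at 39.4 ± 6.73 CPM in small intestine, 9.25 ± 0.471 CPM in MLN and 4.02 ± 0.546 CPM in spleen and ITGAE at 117 ± 32.9, 50.9 ± 3.73 and 49.9 ± 0.777 CPM, so small intestine set most of both differences. TNF was at 158 ± 35.3 against 42.2 ± 18.8 CPM (1.95, edgeR adjusted p = 0.0160). GZMK, a granzyme of memory cells, was at 207 ± 111 against 111 ± 79.5 CPM (1.36, edgeR adjusted p = 0.0240). IFNG (38.2 ± 23.2 against 14.4 ± 10.2 CPM, edgeR adjusted p = 0.147), CXCR6 (0.700), FOXP3 (0.550), KLRB1 (0.727), TGFB1 (0.0981) and LIF (0.690) did not pass, and IL17A had too few counts to be tested. Without brain replicate 1 the edgeR adjusted p was 0.0773 for CCR7, 0.134 for KLF2, 0.0705 for CD69, 0.153 for ITGAE, 0.0511 for ITGA1 and 0.0528 for TNF. Without brain replicate 2 it was 0.105, 0.153, 0.351, 0.187, 0.0936 and 0.134 in the same order, and 0.247 for GZMK. Leaving out MLN replicate 1 ended the calls of KLF2 (0.0515) and CD69 (0.0761), and MLN replicate 2 that of CD69 (0.0689). CD69 and GZMK also lost theirs without small intestine replicate 1 (0.0711 and 0.0684) and small intestine replicate 2 (0.0528 and 0.0528). KLF2 had an edgeR adjusted p of 0.0798 in T-like clusters, 0.0849 without AIF1 in the other-lineage limit and 0.0516 with the gate kept to T-like clusters. ITGA1 had 0.0688 in T-like clusters, and with equal cell numbers ITGA1 had 0.208 and TNF 0.0820. Without the cluster led by GNLY and GZMH the edgeR adjusted p was 0.0984 for KLF2, 0.104 for TNF, 0.0849 for ITGAE, 0.0805 for ITGA1 and 0.1004 for GZMK. S1PR1 passed without MLN replicate 2 (edgeR adjusted p = 0.0303) and with the donor as a block (0.0195), and IFNG without spleen replicate 2 (0.0248) and with the block (0.00718). With no filter on low counts S1PR1 (0.0146) and IFNG (1.97e-14) passed in edgeR, as did IFNG with equal cell numbers (0.0116) and TGFB1 without that cluster (0.0298).

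In CD4 gate cells the effector genes were again higher in brain. GNLY was at 206 ± 5.12 CPM in brain (n = 2), 5.0 ± 0.904 CPM in small intestine and 0 UMIs in MLN (a limit of 0.123 CPM), with an edgeR adjusted p of 6.91e-08. TSPO rose to 124 ± 50 from 17.2 ± 12.6 CPM (log2 fold change 3.46, SE 0.23, edgeR adjusted p = 9.65e-05). PRDM1 rose to 189 ± 69.5 from 22.9 ± 12.0 CPM (3.23, SE 0.31, edgeR adjusted p = 0.0020). NKG7, a cytotoxic granule membrane protein, rose to 218 ± 19.2 from 29.4 ± 29.5 CPM (3.34, SE 0.39, edgeR adjusted p = 0.00486). CCL4 stood at 118 ± 112 against 1.46 ± 1.41 CPM (6.45, SE 0.80, edgeR adjusted p = 0.0106), with 11.9% of its brain level predicted to come from microglia-like cells. TRAF4 fell to 12.7 ± 5.06 from 173 ± 86.8 CPM (-3.52, SE 0.35, edgeR adjusted p = 0.00129). CREM fell to 88.3 ± 36.5 from 654 ± 427 CPM (-2.66, SE 0.33, edgeR adjusted p = 0.00345). VPS37B, LYPD3 and ARG2 were lower too (log2 fold changes of -2.48, -3.05 and -4.23). Of 11734 genes tested, 625 were higher and 433 lower in brain (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 685 were lower with the donor as a block. Cytotoxicity had 12 of 17 members higher (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.17e-13, and adjusted p = 0.0512 with an estimated correlation). Type 17 and innate-like genes had 3 of 14 higher (6 adjusted over the list alone; camera adjusted p = 0.000926, and adjusted p = 0.455 with an estimated correlation). The fetal program had 4 of 11 lower (5 adjusted over the list alone; camera adjusted p = 0.000995, and adjusted p = 0.154 with an estimated correlation). Homing (9 of 17 higher, 1 lower), memory and activation (9 of 18 higher, 2 lower), interferon response (7 of 21 higher), cholesterol synthesis (3 of 21 lower) and glycolysis (3 of 20 lower) were the other called lists. Their camera adjusted p-values were 8.78e-07, 0.000382, 1.18e-05, 0.00282 and 0.0131, with adjusted p = 0.154, 0.455, 0.664, 0.455 and 0.455 with an estimated correlation. Adjusted over the list alone, these counts were 12 and 2, 11 and 3, 11, 6 and 4. The brain cells numbered 79 and 302: 288 genes were higher and 120 lower without brain replicate 1, 19 and 14 without brain replicate 2, and 404 were higher without MLN replicate 1. With 79 cells per library 254 were higher and 195 lower, with no filter on low counts 1073 and 1055, and without the cluster led by GNLY and GZMH 81 and 164. The edgeR adjusted p without brain replicate 2 was 0.114 for CCL4, 0.0967 for NKG7, 0.0702 for PRDM1, 0.217 for ARG2, 0.113 for LYPD3 and 0.101 for VPS37B. The camera adjusted p was then 0.399 for type 17 genes and 0.506 for interferon response. ARG2 also lost its call without brain replicate 1 (edgeR adjusted p = 0.0983) and small intestine replicate 2 (0.0542), and CCL4 without spleen replicate 2 (0.05003). Without that cluster the edgeR adjusted p was 0.0673 for CCL4, 0.727 for NKG7 and 0.0914 for ARG2, and the camera adjusted p was 0.0975 for cytotoxicity, 0.269 for homing, 0.649 for type 17 genes, 0.205 for interferon response, 0.570 for the fetal program and 0.967 for memory, with its direction turned.

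In CD8 gate cells the granule genes were again higher in brain. GZMH was at 371 ± 224 CPM in brain and 1.17 ± 1.10 CPM in the periphery (log2 fold change 8.49, SE 0.75, edgeR adjusted p = 0.00241). GNLY was at 1204 ± 448 against 34.0 ± 27.4 CPM (5.77, SE 0.27, edgeR adjusted p = 2.51e-05). GZMB, encoding granzyme B, was at 174 ± 157 against 4.68 ± 3.15 CPM (5.21, SE 0.66, edgeR adjusted p = 0.00612). CCL4L2 was at 304 ± 216 against 17.1 ± 11.8 CPM (4.26) and CCL3 at 129 ± 88.8 against 4.39 ± 4.73 CPM (5.53). RNA of microglia-like cells was predicted to give 21.8% of the brain level of CCL4L2 and 51.8% of that of CCL3 in this gate. FLT1, a receptor of vascular endothelial growth factor, fell to 3.47 ± 2.29 from 52.5 ± 13.1 CPM (-3.56, SE 0.44, edgeR adjusted p = 0.000847). LYPD3 fell to 20.8 ± 8.52 from 249 ± 109 CPM (-3.39, SE 0.44, edgeR adjusted p = 0.0022). HES4 (-3.57), GNG4, a G protein subunit (-3.90), and ARG2, with 3 brain UMIs and 1.39 ± 0.653 against 56.4 ± 37.9 CPM, were lower too. Of 11307 genes tested, 948 were higher and 973 lower in brain (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Cytotoxicity had 14 of 17 members higher (16 adjusted over the list alone; camera adjusted p = 7.9e-15, and adjusted p = 0.175 with an estimated correlation). Memory and activation had 10 of 18 higher and 3 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.000302, and adjusted p = 0.143 with an estimated correlation). Naive and egress genes had 6 of 14 lower (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00371, and adjusted p = 0.270 with an estimated correlation). Interferon response (10 of 21 higher), homing (7 of 15 higher, 1 lower), the fetal program (1 of 12 higher, 5 lower), cholesterol synthesis (4 of 21 lower) and glycolysis (5 of 20 lower) were called too. Their camera adjusted p-values were 2.69e-06, 0.000218, 0.000332, 0.0015 and 0.00423, and adjusted p = 0.391, 0.175, 0.189, 0.322 and 0.355 with an estimated correlation. Their counts adjusted over the list alone were 12, 8 and 1, 1 and 5, 10, and 6. Type 17 genes (5 of 13 higher), NK and innate lymphoid markers (4 of 11 higher), gamma-delta markers (2 of 8 higher, 1 lower) and microglia markers (6 of 7 higher) were also called. Their camera adjusted p-values were 0.0195, 0.00686, 0.0353 and 1.47e-10, with adjusted p = 0.469, 0.322, 0.426 and 0.143 with an estimated correlation. Their counts adjusted over the list alone were 5 and 1, 6 and 2, 6 and 1, and 7. The counts of genes moved to 476 higher and 253 lower without brain replicate 1, 167 and 87 without brain replicate 2, and 480 and 404 with 84 cells per library. They were 356 and 418 without the cluster led by GNLY and GZMH, and 1519 were lower with no filter on low counts. Leaving out brain replicate 2 gave an edgeR adjusted p of 0.105 for CCL3, 0.264 for ARG2, 0.233 for GNG4 and 0.192 for HES4. For ARG2, GNG4 and HES4 it was 0.101, 0.109 and 0.0733 without brain replicate 1. It was 0.0623 and 0.0541 for GNG4 without MLN replicate 1 and 2, 0.0558 and 0.0578 for ARG2 without small intestine replicate 1 and 2, and 0.0591 for CCL3 without small intestine replicate 2. With 84 cells per library the edgeR adjusted p was 0.0555 for GNLY, 0.0856 for GZMB and 0.0754 for GNG4. GNG4 had 0.0571 in T-like clusters and 0.0561 without AIF1 in the other-lineage limit, and ARG2 had 0.0573 with no filter on low counts. The camera adjusted p without brain replicate 2 was 0.527 for interferon response and 0.799 for type 17 genes, with the direction turned. Without brain replicate 1 it was 0.172 for gamma-delta markers. Removing the cluster led by GNLY and GZMH left 30 and 259 brain CD8 gate cells, with medians of 5799.5 and 1654 UMIs. The edgeR adjusted p was then 0.0714 for GNLY, 0.594 for GZMB, 0.0939 for ARG2, 0.104 for GNG4 and 0.0528 for HES4. The camera adjusted p was then 0.341 for naive and egress genes, 0.695 for memory and activation and 0.0746 for the fetal program.

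An interaction test compared the brain difference between the CD4 and CD8 gates. TNF, a proinflammatory cytokine, was at 253 ± 29.3 CPM in brain CD8 gate cells against 18.6 ± 12.2 CPM in the periphery, and at 146 ± 69.9 against 45.3 ± 23.1 CPM in CD4 gate cells. Its log2 brain effect was smaller in the CD4 gate (interaction -1.96, SE 0.17, edgeR adjusted p = 9.08e-06). PDE4B, a phosphodiesterase that degrades cyclic AMP, differed the other way (1.34, SE 0.16, edgeR adjusted p = 0.000522). It was at 258 ± 7.95 against 87.6 ± 29.7 CPM in the CD4 gate and 165 ± 14.8 against 131 ± 23.8 CPM in the CD8 gate. In all, 102 of 12009 genes differed (edgeR quasi-likelihood with the library as a factor, Benjamini-Hochberg adjusted p under 0.05). KLRG1, an inhibitory receptor of effector cells (-1.40, SE 0.17), NCR3, the activating receptor NKp30 (-1.22, SE 0.20), SH3BP5 (-1.12, SE 0.24) and CISH (-1.11, SE 0.24) also had the larger brain effect in the CD8 gate. KLRG1 was at 99.8 ± 41.7 against 77.5 ± 20.9 CPM in the CD4 gate and 199.9 ± 60.5 against 59.8 ± 22.7 CPM in the CD8 gate. KLHL6 (1.26, SE 0.26), SEC14L1 (1.14, SE 0.26) and ARMH1 (1.10, SE 0.19) differed the way PDE4B did. In the CD8 gate they were lower in brain, at 16.5 ± 2.01 against 51.4 ± 23.9 CPM, 43.5 ± 12.9 against 191 ± 80 CPM and 75.0 ± 15.4 against 140 ± 53.5 CPM. Their log2 brain effects in the CD4 gate were -0.45, -1.03 and 0.12. The count was 65 without brain replicate 1, 171 without brain replicate 2, 208 without small intestine replicate 1 and 63 without spleen replicate 1. It was 12 with equal cell numbers, 38 in T-like clusters, 42 with the gate kept to T-like clusters, 48 with AIF1 left out of the other-lineage limit and 322 with no filter on low counts. Without brain replicate 1 the edgeR adjusted p was 0.0700 for KLHL6, 0.234 for SEC14L1, 0.0742 for ARMH1 and 0.165 for SH3BP5. The edgeR adjusted p without brain replicate 2 was 0.310 for KLHL6, 0.415 for SEC14L1, 0.109 for NCR3, 0.137 for SH3BP5 and 0.556 for CISH. SH3BP5 also lost its call without spleen replicate 1 (0.0633) or 2 (0.0577), SEC14L1 without small intestine replicate 2 (0.0562), and CISH without MLN replicate 2 (0.0501), small intestine replicate 2 (0.0775) or spleen replicate 2 (0.0527). Of the 9 named genes, PDE4B (edgeR adjusted p = 0.188), SEC14L1, ARMH1, SH3BP5 and CISH lost their calls in T-like clusters, and the same 5 without AIF1. With equal cell numbers all but TNF and PDE4B lost theirs, and with the gate kept to T-like clusters SEC14L1, SH3BP5 and CISH did.

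Brain T cells also stood apart from T cells of the small intestine, the other non-lymphoid organ, with more RNA of effector genes and less of a hypoxia-response factor. GNLY was at 574 ± 201 CPM in brain against 6.92 ± 0.453 CPM in small intestine (n = 2 each; log2 fold change 6.36, SE 0.35, edgeR adjusted p = 0.000127). TSPO was at 107 ± 24.3 against 3.20 ± 0.600 CPM (5.10, SE 0.28, edgeR adjusted p = 0.000119). CISH was at 105.4 ± 31.0 against 3.6 ± 0.868 CPM (4.86, SE 0.56, edgeR adjusted p = 0.00174). GZMH and CCL4 were higher as well, with log2 fold changes of 8.86 and 4.80. EPAS1, a hypoxia-inducible transcription factor, was lower in brain, at 5.07 ± 2.41 against 167 ± 111 CPM (-4.87, SE 0.59, edgeR adjusted p = 0.00205). TRAF4 (15.9 ± 7.48 against 324 ± 150 CPM), HES4 (4.23 ± 3.6 against 290 ± 151 CPM), GNG4 (3.02 ± 1.90 against 170 ± 88.5 CPM) and LAYN (3.29 ± 3.86 against 75.5 ± 40 CPM) were lower too. In total 1880 genes were higher and 2432 lower in brain (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), against 681 and 1050 in brain minus the mean of MLN and spleen. Cytotoxicity (13 of 17 higher), homing (12 of 20 higher, 2 lower) and microglia markers (7 of 8 higher) were called upward by camera. Their camera adjusted p-values were 3.93e-09, 0.000135 and 1.15e-05, each with an adjusted p = 0.251 with an estimated correlation. Cholesterol synthesis (11 of 21 lower), NF-kB targets (3 of 19 higher, 10 lower), glycolysis (10 of 21 lower) and the fetal program (1 of 12 higher, 4 lower) were called downward. Their camera adjusted p-values were 0.00545, 0.010, 0.0124 and 0.0160, with adjusted p = 0.691, 0.758, 0.639 and 0.251 with an estimated correlation. Adjusted over the list alone, the counts were 16 and 1, 12 and 2, 7, 1 and 12, 3 and 12, 10, and 1 and 4, in that order. Without brain replicate 2 the counts of genes were 850 higher and 828 lower, without small intestine replicate 2 1209 and 1150, without brain replicate 1 995 were lower, and with 250 cells per library they were 1212 and 1244. CCL4 had an edgeR adjusted p of 0.0738 without small intestine replicate 1 and 0.0516 without small intestine replicate 2. That of GNG4 was 0.0600 without brain replicate 2, and LAYN kept its call only without each spleen library (up to 0.109, without small intestine replicate 2).

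As a scale for the brain difference, small intestine was set against the lymphoid organs. EPAS1 was higher in small intestine, at 167 ± 111 against 12.5 ± 3.55 CPM in MLN and spleen (n = 2 and n = 4; log2 fold change 3.79, SE 0.39, edgeR adjusted p = 0.00123). PBX4, a homeobox transcription factor, was at 229 ± 48.9 against 23.5 ± 4.22 CPM (3.30, SE 0.25, edgeR adjusted p = 0.000283). SYTL3, a vesicle-docking protein, was at 472 ± 199 against 58.7 ± 21.8 CPM (3.01, SE 0.42, edgeR adjusted p = 0.00437). PTPN6, the phosphatase SHP-1, was lower at 8.86 ± 1.23 against 81.6 ± 27.2 CPM (-3.20, SE 0.34, edgeR adjusted p = 0.00082). Lower too were SIRPG, a ligand of CD47, at 19.2 ± 2.16 against 145 ± 29 CPM (-2.92), TSPO (-2.91), SH3BP1 (-2.89) and FCER1G (-2.91). In this comparison 1541 genes were higher and 1659 lower in small intestine (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Camera called interferon response (6 of 22 higher, 1 lower), NF-kB targets (10 of 19 higher) and cytokines (8 of 17 higher, 2 lower) upward at adjusted p-values of 0.00234, 0.00337 and 0.0119. Cytotoxicity (1 of 17 higher, 5 lower), naive and egress genes (3 of 14 higher, 8 lower) and immediate early and stress genes (5 of 22 lower) went downward at 0.0119 each. All 6 calls were lost with adjusted p = 0.788 with an estimated correlation. Adjusted over the list alone, the counts were 7 and 1, 10 and 1, 8 and 3, 1 and 8, 3 and 8, and 5. The count of higher genes was 662 without small intestine replicate 2, 1005 and 996 without MLN replicate 1 and 2, 982 without spleen replicate 1 and 829 with 250 cells per library. That of lower genes was 796 and 1015 without small intestine replicate 2 and 1, 1088 without spleen replicate 1 and 904 with equal cells. GNG4 and HES4, higher in small intestine by 3.61 and 3.37 on the log2 scale, lost their calls without small intestine replicate 2 (edgeR adjusted p = 0.0503 and 0.0710). GNG4 did so also without MLN replicate 1 (0.0519) and HES4 without spleen replicate 2 (0.0516), and FCER1G did so with 250 cells per library (0.0555).

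Whether brain T cells differ from lymphoid T cells in the way small intestine T cells do was examined across genes. The log2 fold changes of brain minus MLN and of small intestine minus spleen, which share no library, had a Pearson r of -0.116 and a Spearman rho of -0.102 over 14440 genes (covariance -0.144), and genes are not independent replicates. In 20 simulations without any effect r lay between -0.0395 and 0.0440. With brain minus spleen and small intestine minus MLN r was -0.00888, over genes of at least 30 CPM it was -0.193, and it was -0.0399 without donor 2. Against shared lymphoid libraries r was -0.0202 (covariance -0.0227), where shared libraries alone gave 0.187 on average (0.162 to 0.230; covariance 0.0640). Of the 681 genes higher in brain than in the lymphoid organs, 91 were also higher in small intestine and 96 lower, where independent lists of these sizes would share 72.7 and 78.2. Of the 1050 lower genes, 146 were also lower and 165 higher in small intestine, against 120.6 and 112.1. The shared lymphoid libraries, which alone gave a positive r, raise the same-direction counts, not the opposite ones.

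CD4 gate cells made up 31.6% (95% exact binomial interval 25.9 to 37.8) and 24.1% (21.8 to 26.6) of T gate cells in brain replicates 1 and 2. The means were 27.9 ± 5.27% in brain (n = 2) and 24.3 ± 3.10% in the periphery (n = 6). The difference of 3.56 percentage points did not pass (two-sided exact permutation p = 0.357 over 28 splits, smallest possible 0.0357). Brain cells were shallower, so each cell was also thinned to 2000 UMIs, leaving out 33 and 395 brain cells and 8 to 426 elsewhere. The thinned shares were 17.2 ± 3.11% in brain and 9.69 ± 2.36% in the periphery, with both brain libraries above all 6 peripheral ones (difference 7.46, exact permutation p = 0.0357, the smallest possible). With the donors kept apart the 16 splits allow no p under 0.0625, which is the value of the thinned share, so this permutation cannot pass the threshold. Among thinned T gate cells with a CD8 UMI, in which CD4 RNA should be missing, a CD4 UMI was seen in 0.617 ± 0.873% in brain and 1.56 ± 1.16% in the periphery (exact permutation p = 0.357). With the T gate kept to T-like clusters the unthinned shares were 33.7 ± 1.20% and 24.5 ± 3.18% (difference 9.19, exact permutation p = 0.0357, and 0.0625 with the donors kept apart). Leaving out brain replicate 1 turned the unthinned difference to -0.168, and it was 7.29 without brain replicate 2. CD8 gate cells made up 34.8 ± 1.73% of T gate cells in brain and 26.3 ± 9.82% in the periphery (difference 8.54, exact permutation p = 0.286; thinned 7.16, exact permutation p = 0.357).

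**Figure D3:**
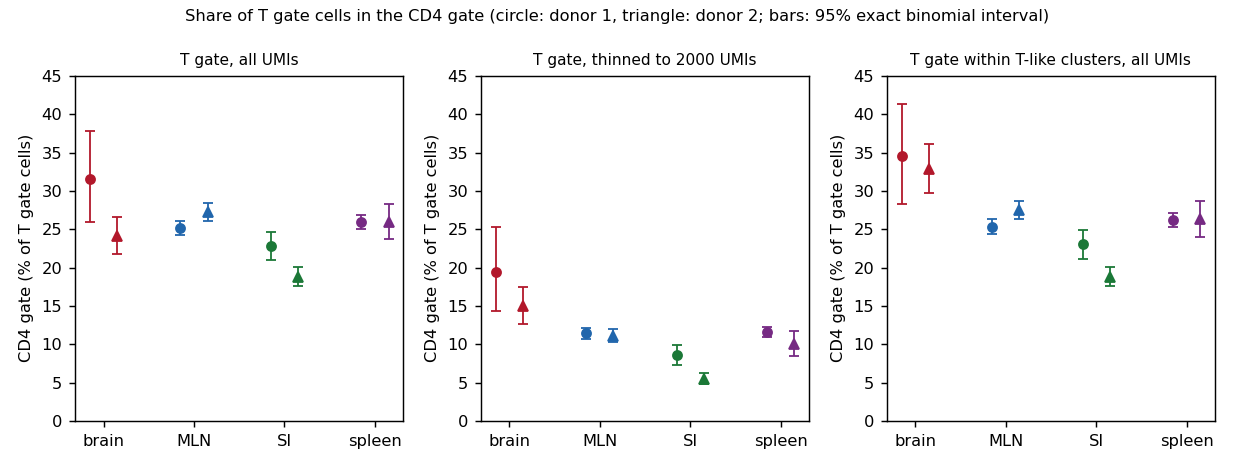
Share of T gate cells in the CD4 gate (vertical axes, %) per library of brain, mesenteric lymph node (MLN), small intestine (SI) and spleen, for donor 1 (circles) and donor 2 (triangles) with 95% exact binomial intervals, for all UMIs, for cells thinned to 2000 UMIs and for T gate cells within T-like clusters. Both brain libraries lie above all peripheral libraries in the last 2 panels, with means of 17.2% and 33.7%.

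Clustering of 50026 barcodes gave 30 clusters, of which 24 were T-like (CD3D in at least 50% of cells, fewer than 2 markers of another lineage among the 10 leading genes, and no low UMI count) and 9 could be named from markers chosen beforehand. The regulatory T-like cluster, led by CTLA4, FOXP3, TIGIT and LRRC32, held 5.10 ± 0.159% of T-like cells in brain, 9.34 ± 4.25% in MLN, 2.98 ± 0.149% in small intestine and 9.46 ± 1.68% in spleen (n = 2 each). The CD8 T-like clusters 1 and 5, whose leading genes include CD8B, CD8A and LINC02446, held 9.99 ± 0.473% in brain, 28.1 ± 0.313% in MLN, 0.416 ± 0.0234% in small intestine and 21.3 ± 1.06% in spleen. Their share was lower in brain than in MLN and spleen, but brain CD8 gate cells also lay in other clusters. Cycling-like cells, led by genes such as MKI67 and TYMS, made up 1.01 ± 0.546% in brain, 2.43 ± 0.495% in MLN, 4.51 ± 2.14% in small intestine and 2.37 ± 0.478% in spleen. They lay in clusters 13 and 26. Clusters 17 and 23, led by TYMS and MCM2 but unnamed, share TYMS with them. Together the 4 clusters held 1.52 ± 1.27% in brain, 5.04 ± 0.651% in MLN, 4.65 ± 2.34% in small intestine and 5.45 ± 1.76% in spleen. No test was planned for these shares. A cluster led by GNLY and GZMH held 50.4% and 49.0% of T gate cells of brain replicates 1 and 2. Without its cells 491 genes were higher and 965 lower in the brain T gate by edgeR. The brain cells left then had medians of 6425 and 1743 UMIs. T gate barcodes outside T-like clusters made up 13.2% and 32.1% of the brain gate and 0.255 to 4.91% elsewhere, and with T-like clusters in place of the gate 1065 genes were lower in brain.

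The TCR-enriched libraries held 330 to 13088 barcodes and 164905 to 2314398 UMIs. In brain, 100% and 99.2% of their barcodes were also in the gene-expression library of the same tissue and donor, against at most 3.33% in any other library. The share was 99.4 to 99.9% in the peripheral libraries except small intestine replicate 1, at 89.4% (95% exact binomial interval 88.2 to 90.6). Each barcode was assigned its leading TRBV gene, the variable segment of the TCR beta chain with most UMIs, and libraries were thinned to 292 barcodes. The effective number of TRBV genes (the exponential of the Shannon entropy) was 29.8 ± 1.22 in brain (n = 2) and 27.3 ± 1.22 in the periphery (n = 6). The difference of 2.44 did not pass (two-sided exact permutation p = 0.107, smallest possible 0.0357). It was 1.57 without brain replicate 2, passed without spleen replicate 2 (2.78, exact permutation p = 0.0476, the smallest possible there) and was 1.24 without thinning (exact permutation p = 0.393). Of T gate cells in T-like clusters, 85.7% and 85.7% had a leading TRBV gene in brain and 61.8 to 84.4% elsewhere. Only 15.2% and 1.99% of the brain T gate barcodes outside those clusters did.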

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

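The settings without AIF1, without the cluster led by GNLY and GZMH and with the gate kept to T-like clusters were chosen after the data were seen, and the other tests of this part before. The interaction test found 102 genes whose brain effect differed between the CD4 and CD8 gates (edgeR), and 9 of them met the naming rule. The brain effect in the CD4 gate minus that in the CD8 gate was -1.96 for TNF, -1.40 for KLRG1, -1.22 for NCR3, -1.12 for SH3BP5 and -1.11 for CISH on the log2 scale, and 1.34 for PDE4B, 1.26 for KLHL6, 1.14 for SEC14L1 and 1.10 for ARMH1. Of these 9 genes, 5 lost their calls in T-like clusters, 5 without AIF1, 5 without the cluster led by GNLY and GZMH, 3 with the gate kept to T-like clusters and 7 with equal cell numbers. In the TCR-enriched library of small intestine replicate 1, 10.55% of barcodes were not in the gene-expression library of the same tissue and donor, above the limit that a count of 0 allows.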

How the results depend on the processing

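Chosen after seeing the data were the limit without AIF1 and the gate within T-like clusters (both also thinned), T-like clusters thinned, and doublets kept. So were the removal of the cluster led by GNLY and GZMH, fry, and the correlation with shared lymphoid libraries. The donor block on the thinned share and the share within T-like clusters was too. Of 129 results on named genes, 129 kept direction and call with a 5% mitochondrial limit, 127 with RLE, 126 with no filter on low counts, 128 with doublets kept, 126 with DESeq2 (all that it gave a value for), 123 of 128 with the gate within T-like clusters, 119 without AIF1, 115 in T-like clusters, 116 of 120 with the donor as a block and 100 of 121 with equal cell numbers. Leaving out brain replicate 1 ended 37 of these calls and brain replicate 2 61, against 5 to 18 for peripheral libraries. The removal of the cluster led by GNLY and GZMH ended 37 of 128 and turned 1, FGFBP2, to -1.46. In the T gate the calls of FGFBP2, IL22, LRRC32, AREG, HSPE1, ANKRD37, KLF2 and ITGA1 ended in T-like clusters, those of FGFBP2, IL22, AREG and KLF2 without AIF1, those of IFIT3 and KLF2 with the gate within T-like clusters, and that of PFKFB3 with RLE. With equal cell numbers 8 ended there, including TNFRSF1B, TOX2, SPP1, TNF, PFKFB3, ANKRD37 and ITGA1, and IFNG passed. The removal of the cluster led by GNLY and GZMH ended 23 of 71 T gate calls, and TGFB1 passed. Where a brain library was left out, the other has no replicate of its own and is assumed to vary like the other groups. The cause was not tested for any value below, except that fewer cells or libraries were used by construction.

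With equal cell numbers, the genes higher and lower in brain were 771 and 748 in the T gate, 254 and 195 in the CD4 gate, 480 and 404 in the CD8 gate and 1212 and 1244 against small intestine, those of small intestine against lymphoid organs 829 and 904, and the interaction 12. Without the cluster led by GNLY and GZMH they were 491 and 965 in the T gate, 81 and 164 in the CD4 gate and 356 and 418 in the CD8 gate. With no filter on low counts 1923 genes were higher in the T gate, 1073 and 1055 were higher and lower in the CD4 gate, 1519 were lower in the CD8 gate and the interaction had 322. T-like clusters gave 1065 lower genes in the T gate and 38 in the interaction, which had 42 with the gate within T-like clusters and 48 without AIF1. With the donor as a replicate block 685 genes were lower in the CD4 gate, FGFBP2 and HES4 lost their edgeR calls, S1PR1 and IFNG gained theirs, and the NF-kB list gained a camera call in the T gate (adjusted p = 0.0131) and the CD4 gate (0.0160). Among the named genes and lists it was run on, the block changed no other call. Over all genes of the T gate it called 3723, of which 2863 were among the 2868 called without it. It was not run for the interaction, whose library factor holds the donor.

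Leaving out each library gave, for higher and lower genes, 175 to 1379 and 79 to 1635 in the T gate, 19 to 579 and 14 to 602 in the CD4 gate, 167 to 958 and 87 to 990 in the CD8 gate, 850 to 1887 and 828 to 2404 against small intestine, 662 to 1567 and 796 to 1722 for small intestine against lymphoid organs, and 63 to 208 for the interaction. The difference in the CD4 share ranged from -0.168 to 7.29 percentage points and that in effective TRBV genes from 1.57 to 3.31. The correlation, for which whole donors were left out, ranged from -0.0825 to -0.0399. It was -0.00888 with the lymphoid organs exchanged, -0.193 over genes of at least 30 CPM and -0.0202 with shared lymphoid libraries. The difference in the CD4 share was 7.46 thinned, 8.38 in T-like clusters, 9.19 with the gate within them, and 4.73, 7.62 and 4.79 in the thinned forms of T-like clusters, of the gate within them and of the gate without AIF1, each with an exact permutation p of 0.0357. With the donors kept apart p was 0.0625, the smallest possible, for the thinned share and for the gate within T-like clusters. Cluster borders moved with floating-point rounding, and under other rounding the thinned form of T-like clusters missed the threshold and LRRC32 in T-like clusters (edgeR adjusted p = 0.0501 here) passed it. The TRBV difference passed without spleen replicate 2. With an estimated correlation 0 lists passed in the T, CD4 and CD8 gates, where camera called 10, 8 and 12. Without the cluster led by GNLY and GZMH 3 passed in the CD4 gate and 7 in the CD8 gate, and without a brain library 12 to 13, 10 to 10 and 9 to 13 in the 3 gates. Memory and activation turned without that cluster in the T gate (camera adjusted p = 0.700) and the CD4 gate (0.967), and type 17 genes turned without brain replicate 2. Over both brain libraries the camera adjusted p was 0.000665 to 0.968 (gene list: type 17 and innate-like, T gate) and 0.000226 to 0.799 (gene list: type 17 and innate-like, CD8 gate).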

Other observations

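The tests on cells without a TCR, on tissue handling and both tests on the CD4 share were chosen after the results were seen. Cells of the brain cluster led by GNLY and GZMH carried TCR beta transcripts: 82.5% of its 126 T gate cells in brain replicate 1 and 86.9% of its 613 in replicate 2 had a leading TRBV gene, against 90.1% and 82.6% of the T gate cells of other T-like clusters. Drawn down to 82 and 195 cells, its effective number of TRBV genes was 21.9 and 29.2 against 26.9 and 28.8 in those, and its leading TRBV gene took 10.6% and 10.9% of cells against 9.76% and 7.69%.

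The cytotoxicity genes were higher in the brain T gate, with a median log2 fold change of 2.94 over the 13 called genes (1.88, with 7 called, without the cluster led by GNLY and GZMH, which such genes define). Microglial RNA was predicted to give 3.04% of the difference of the summed list, and 13 of 13 genes stayed called within T-like clusters, which argues against it as the whole cause. With equal cells 13 stayed called (median 3.15), but fewer in brain need not shift a median, so this cannot tell. Cells without a TCR, such as NK cells, which the CD3+ sort should have removed, stay open: 82.54% and 86.9% of the cluster had a leading TRBV gene, against 5 of 33 and 8 of 402 shallower T gate barcodes outside T-like clusters, and the share lay above the background in microglia-like cells outside the T gate in brain replicate 2 (7 of 53, upper 95% exact limit 25.3%) but not in replicate 1 (6 of 9, upper limit 92.5%). An untested biological difference also stays open.

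For the 275 genes of the naming rule that were lower in brain than in the 3 peripheral libraries of the same donor, in both donors, the median log2 fold change was -1.32. Dilution of the brain gate by mixed clusters is argued against by a median of -1.34 within T-like clusters. The cluster led by GNLY and GZMH is argued against as the whole cause by a median of -1.25 without it. Tissue handling before the sort cannot be told apart from tissue, with no record of it, and the immediate early and stress list had a camera adjusted p of 0.683. Heat shock clusters were picked after values were seen. Cluster 11 (HSPA1B, HSPA6, HSPA1A) held 27.7% and 13.9% of brain T-like cells and 0.0197 to 6.93% elsewhere. Cluster 3 (HSPA1A, HSPH1) held 1.25% and 0.279%, 33.7% in spleen replicate 1 and 0 to 4.73% elsewhere, so 1 library sets it. A biological difference also stays open.

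The CD4 gate share was higher in brain after thinning but not before. Microglial CD4 RNA is argued against by the share of brain CD8-bearing cells with a CD4 UMI, whose upper 95% exact limit was 2.88% in thinned cells (3 of 302), under the thinned difference of 7.46 points. This covers thinned cells alone: unthinned, 10.2% of such cells had a CD4 UMI in brain replicate 2 and 2.33% in replicate 1, against 2.82 to 9.21% elsewhere. Low-UMI barcodes of mixed clusters could have lowered the unthinned brain share, since the difference was 9.19 points with the gate kept to T-like clusters. A biological difference in the share stays open, as untested.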
